A study of Gallus gallus with 36 samples.

How the data were processed

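RNA from chicken spleens was measured on 36 Agilent 1-colour arrays. Per the labels, 26 arrays came from birds challenged orally with *Salmonella* Pullorum and 10 from mock-challenged controls, at 9 times after the challenge. Each challenged array held a pool of 2 birds and each control array a pool of 3 birds, so the replicates were pools and the spread between arrays understated that between single birds. The scanner files held intensity values per spot which, per the file headers, the authors made with Agilent Feature Extraction 10.7.1.1. The processing notes of the submitters name version 9.5 of that program. The processed intensity was background-subtracted and detrended within each array, and was not scaled between arrays. The deposited table held log2 values that the authors had normalized between arrays. Its columns had medians of 7.786 to 7.787 and 75th percentiles of 10.232 to 10.234, as quantile normalization gives, and across probes each column had a correlation of 0.9959 to 0.9999 with the log2 scanner value of its array.

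The scanner intensities were the starting point. Spots of 50 probes printed more than 1 time were averaged, which left 43603 probes from 43803 spots. The log2 processed intensity of each array was reduced by its 75th percentile, so a level of 0 lies at that percentile. Probes well above background on at least 3 of the 36 arrays were kept (39827). A gene with several kept probes was represented by the probe with the highest mean level, which gave 25024 genes. In the 8287 genes with several kept probes the median correlation between probes was 0.636, and it lay below 0 for 792 genes. Names came from RefSeq accessions of the array file matched to the reference names (14579 probes), from a current symbol in the array file (9520), from an older symbol updated through the table (384), from a symbol the table lacks (984) or from an accession that gave a LOC number only (383). The remaining 17753 probes had no symbol and kept the name of their feature, and the probes made 27754 features in all. The array was designed on an older chicken assembly than that of the table, so no coordinates are given.

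The precision rests on the number of arrays and on the signal over background. The 75th percentile of the processed intensity ranged from 512 to 2470 between arrays (median 1260), and 72.9% to 88.2% of the spots were well above background (median 81.7%). The median local background was 20.5 to 31, and no spot was saturated. The arrays lay on 9 slides scanned on 2 days. The first day held every control array and the challenged arrays of 2 and 4 hpi, and the second day held the challenged arrays from 8 hpi on.

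Comparisons were made in limma 3.58.1 under R 4.3.3 with data.table version 1.17.8. A model with 18 group means over the 36 arrays gave the 9 differences at single times, the mean difference of the hours stage (2, 4 and 8 hpi and 1 dpi), that of the days stage (3 to 21 dpi), that of all times, and the difference between the stages. The lone control array of most times had no spread of its own and was assumed to vary like the replicated groups. The change with age was fitted in the 10 control arrays as 6 days-stage against 4 hours-stage arrays, and in the 26 challenged arrays from 9 group means. Residual degrees of freedom were 18, 8 and 17. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05 within a comparison, and 15 comparisons were made. Values printed as ± are standard errors of the fitted difference, in log2. Where no array of 1 group was well above background, the fold is given as a lower bound, with values under the lowest level of any probe well above background on that array raised to it.

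Of 20 gene lists, 19 were tested in 4 comparisons with limma's camera at a preset correlation of 0.01, which made 76 tests, adjusted over the lists within each comparison. They covered inflammatory cytokines and chemokines, NF-kB feedback, pattern recognition receptors, interferon-stimulated genes, antimicrobial peptides and heterophil genes, acute phase proteins, complement, iron and heme handling, antigen presentation, T and NK cells, B and plasma cells, macrophages and dendritic cells, erythroid cells, thrombocytes, the cell cycle, heat shock and immediate early genes, pancreas, liver, and muscle and stroma. A list of W-linked genes had 3 measured members and was described only. A list score is the median over members of the level minus the member's median over the 36 arrays. Camera sets a list against all other genes, so a list near 0 can pass as higher where most genes lie lower.

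The comparisons, stages, lists, tests and the rule for named genes were fixed before the data were examined. By that rule a named gene has a symbol and passed the test, and the 12 largest rises and falls were taken for each stage among genes with 1 sign at every time of that stage. The same number was taken for the age change, 8 each way for the stage difference, and 3 each way per time with every challenged array on 1 side of the control. The examples of a list are its 3 members with the smallest p.

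The steps were tested on simulated data, with 200 of 24583 genes changed. At a log2 change of 2, 95% were recovered in the hours stage, 95% in the days stage, 67% at 1 dpi, 88% in the stage difference and 80% in the control age change. At a log2 change of 1 the shares were 68%, 64%, 12%, 44% and 45%. For all times 98% and 83% were recovered. False calls numbered 10 of 173 in the hours stage, 7 of 166 in the days stage and 8 of 189 for all times. They were 4 of 83 at 1 dpi, 13 of 145 in the stage difference and 5 of 130 in the control age change. The simulated noise was independent between genes and equal in both groups. It held no shift between slides or scan days, no patch of spots and no other tissue, so these shares do not cover such sources of calls. For the control age change each simulated gene had the same mean at every time apart from the added change. Its shares of 80% and 45% thus do not cover genes that change between the times of a stage.

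Alternatives planned in advance were quantile normalization, normexp background correction (offset 50), the deposited table, no filter, a filter at 18 arrays, the mean over probes, an added log2 difference of at least 1, trend and robust options, other models, a replicate block, a slide block for the stages, all times and the age changes, and leaving out arrays or times. Chosen after the data were seen were a slide block at single times and for the lists, terms for the scan day, masking of a patch of spots, leaving out arrays with a pancreas or liver list score over 2, leaving out the dimmest array, and the brighter 3 of 5 brightness classes. The arrays with high scores included the lone controls of 2 and 4 hpi, so without them these times dropped out of the challenge comparisons. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.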

Results

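The series followed gene expression in the spleen of Guangxi Yellow chicks after oral infection with *Salmonella* Pullorum, the bacterium of pullorum disease, which causes heavy losses in young chicks. Chicks were challenged on the second day of life, and controls were mock-challenged with water. Spleens were taken at 2, 4 and 8 hours post infection (hpi) and at 1, 3, 5, 7, 12 and 21 days post infection (dpi). Each time had 3 challenged arrays and 1 control array, except 21 dpi, which had 2 and 2 by the labels. The hours stage (2 hpi to 1 dpi) thus held 12 challenged and 4 control arrays, and the days stage (3 to 21 dpi) held 14 and 6.

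The 75th percentile of the processed intensity was 512 to 2470 over the 36 arrays. The dimmest array was challenged 8 hpi replicate 3, with 73.9% of its spots well above background. The best correlation of an array with any other lay between 0.969 and 0.990 across probes, which are not independent replicates. All control arrays and the challenged arrays of 2 and 4 hpi were scanned on 1 day, and the challenged arrays from 8 hpi on were scanned on another. From 8 hpi on the challenge and the scan day could therefore not be told apart. At no time did challenged and control arrays share a slide. At 2 and 4 hpi too, the challenge could thus not be told apart from the slide.

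The first question was how the spleen differed in the first hours after the challenge. In the hours stage TRIB1, a pseudokinase that curbs MAP kinase and C/EBP signalling, rose by 0.84 ± 0.17 (log2; 1.79-fold, n = 12 and 4, adjusted p = 0.0244) and was higher in 12 of 12 challenged arrays. HIVEP3, a zinc finger protein that binds kappa-B motifs, rose 1.72-fold (0.78 ± 0.17, adjusted p = 0.0371). IDI1 of cholesterol and isoprenoid synthesis rose 1.76-fold (0.81 ± 0.16, adjusted p = 0.0203), and the ubiquitin ligase RNF144B rose 1.53-fold (0.62 ± 0.13, adjusted p = 0.0337). The vesicle traffic GTPase RAB8B and the nuclear pore protein NUP153 rose by 0.46 ± 0.09 and 0.39 ± 0.08, each in 12 of 12 challenged arrays, but 1 of 4 other NUP153 probes had the same sign. HECW2, another ubiquitin ligase, rose 2-fold (1.00 ± 0.17, adjusted p = 0.00645), but its difference was 3.35 at 1 dpi and 0.22 over the other times of the stage (adjusted p = 0.753). MEGF9 rose by 0.48.

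Among the falls, ALB, which encodes the serum albumin made in liver, fell by 2.63 ± 0.45 (6.21-fold, adjusted p = 0.00651) and was lower in 12 of 12 challenged arrays. HPD, an enzyme of tyrosine breakdown in liver, fell 2.53-fold (adjusted p = 0.00127), and the retinol carrier gene RBP4A fell 2.39-fold (adjusted p = 0.0488). PRPS2, which makes the ribose phosphate donor for nucleotide synthesis, fell 3.25-fold (adjusted p = 0.00108). The p53-induced stress gene TP53INP1 fell by 0.73 ± 0.15 and the collagen-binding integrin gene ITGA11 by 0.73 ± 0.15. RAB11FIP3, SLC46A3, PARP16 and ZBTB25 fell by 1.14, 0.82, 0.57 and 0.56, and the other probe of RAB11FIP3 had the opposite sign. SLCO1A2, a transporter of organic anions, and GPRIN2 fell by 1.57 and 1.53, and each was well above background on 1 of 12 challenged and 2 of 4 control arrays. Several falls rested on a lone control: without 2 hpi ALB, PRPS2, HPD, RBP4A and RAB11FIP3 had -1.77, -1.125, -0.71, -0.68 and -0.69 (adjusted p = 0.21, 0.105, 0.282, 0.488 and 0.289). Without 4 hpi GPRIN2 had -0.94 (0.225), and without 1 dpi SLCO1A2 and ZBTB25 had -0.82 and -0.36 (0.48 and 0.416). RALB, BAZ2B, ABCG4 and USP31 were called higher by 2.91, 2.72, 1.71 and 1.70, but their spots lay in a patch without signal on the 1 dpi control array, and without 1 dpi the differences were 0.06, 0.30, 0.05 and 0.48.

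The liver markers, proteins that hepatocytes secrete or use, had the lowest p of the 19 lists in the hours stage. Of 26 measured, 2 fell (ALB and HPD), or 10 adjusted over the list alone, with a median difference of -0.99 (adjusted p = 4.57e-09, and adjusted p = 0.0816 with an estimated correlation). The liver list score of the 2 hpi control array was 2.81, the highest of the 36. The acute phase list, which shares the fibrinogen genes with it, had a median of -0.73 over 17 members, and 6 fell adjusted over the list alone (adjusted p = 0.000449, and adjusted p = 0.349 with an estimated correlation). FGB of that list had a difference of -2.21 ± 0.54 (adjusted p = 0.0783). Without genes that another list holds its adjusted p was 0.256.

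The inflammatory cytokine and chemokine list lay higher, with 28 of 32 members above the controls and a median difference of 0.58 (adjusted p = 3.74e-06, and adjusted p = 0.526 with an estimated correlation). No member passed alone or adjusted over the list alone. IL4I1, an amino acid oxidase of activated phagocytes, differed by 1.71 ± 0.64 (adjusted p = 0.274), the chemokine gene CCL4 by 1.71 ± 0.68 (adjusted p = 0.31) and IL18 by 0.90 ± 0.31 (adjusted p = 0.228). The median difference of the list was 0.72 at 2 hpi, 0.10 at 4 hpi, 0.37 at 8 hpi and 1.08 at 1 dpi, and it lay between -0.29 and 0.15 from 3 dpi on. Within the first scan day (2 and 4 hpi) it was 0.56, and at 8 hpi and 1 dpi it was 0.68.

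Other lists that passed in the hours stage had smaller medians. The NF-kB list had a median of 0.28, with 3 members higher and 1 lower adjusted over the list alone (adjusted p = 0.00342, and adjusted p = 0.667 with an estimated correlation). TRAF3 differed by 0.63 ± 0.17 and the cytokine signalling inhibitor SOCS3 by 1.33 ± 0.39 (adjusted p = 0.107 and 0.158). Within the first scan day the NF-kB list had a median of 0.03 (adjusted p = 0.745). The interferon-stimulated list had 28 of 32 members higher with a median of 0.16 (adjusted p = 0.0048, and adjusted p = 0.846 with an estimated correlation). Heat shock and immediate early genes had a median of 0.23 (adjusted p = 0.0105, and adjusted p = 0.667 with an estimated correlation), turned to -0.01 at 2 and 4 hpi (adjusted p = 0.471), and gave 0.053 with normexp correction. In the macrophage list 1 of 33 members was called higher, MAF, whose spot lay in the patch (1 higher and 1 lower adjusted over the list alone, adjusted p of the list = 0.241). In the T and NK cell list 1 member passed adjusted over the list alone, and no member of the other lists did. Their adjusted p were 0.191 for T and NK cells, 0.599 for pattern receptors, 0.628 for antimicrobial peptides, 0.172 for complement, 0.628 for iron handling, 0.195 for antigen presentation, 0.751 for B cells, 0.628 for erythroid cells, 0.628 for thrombocytes, 0.365 for the cell cycle, 0.172 for pancreas and 0.599 for muscle and stroma. The 3 W-linked genes, which mark female birds, had a median of -0.26 and were not tested.

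**Figure D1:**
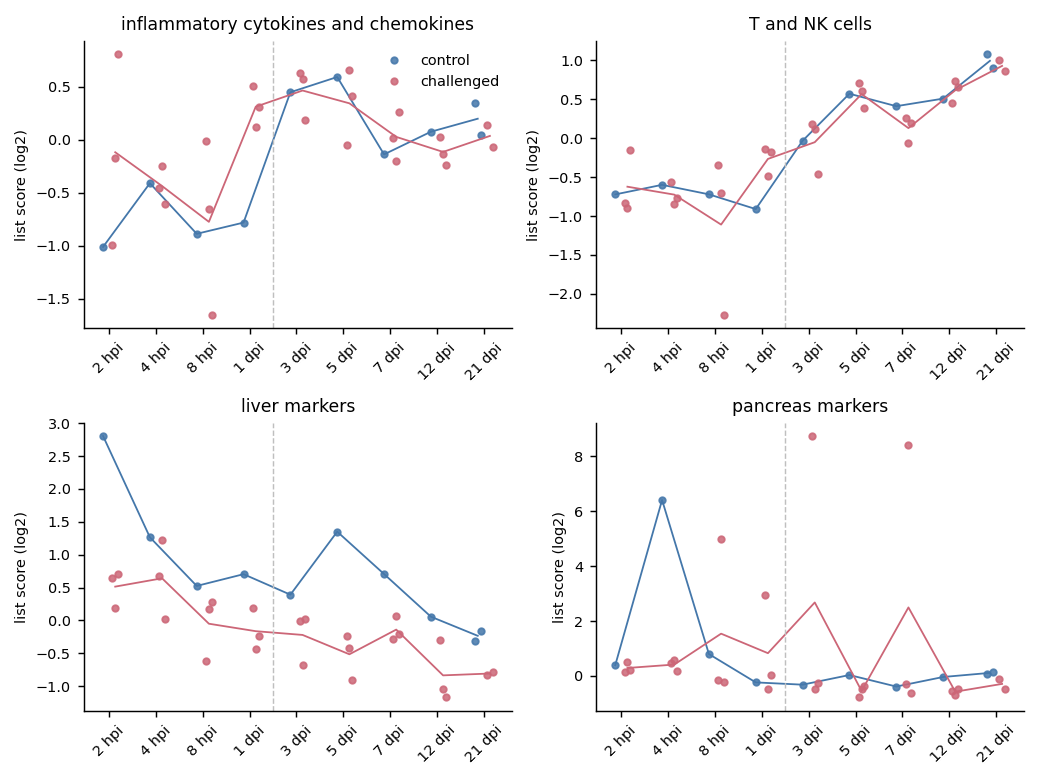
List scores (log2, y axis; median over members of the level minus the member's median over the 36 arrays) at each time (x axis), with 1 point per array, lines through the group means and a dashed line between the stages. The liver score is highest in the 2 hpi control (2.81), and the pancreas score is over 2 in 5 arrays (6.41, 5.00, 2.94, 8.74 and 8.41).

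In all, limma called 61 genes higher and 50 lower in the hours stage (111 of 24970, 2993 at an unadjusted p under 0.05). With slide as a random block fewer were called, as given below. With the patch masked 12 were higher and 26 lower, without 1 dpi 11 were called, on the first scan day alone 6 were higher and 11 lower, and an additive model of time and challenge called 0 (2353 at an unadjusted p under 0.05). HECW2, TRIB1 and IDI1 kept their calls with the patch masked (adjusted p = 0.028, 0.0471 and 0.0424), and HIVEP3, RNF144B, RAB8B and NUP153 did not (0.0605, 0.0583, 0.0522 and 0.057). MEGF9, RBP4A, TP53INP1, SLC46A3 and PARP16 lost theirs too (0.0706, 0.0709, 0.0587, 0.0667 and 0.0626), with differences equal to those without the mask. Among the 6 arrays with a pancreas or liver score over 2 were the lone controls of 2 and 4 hpi. Without the 6 arrays the stage therefore held 8 hpi and 1 dpi alone, which is another comparison. It gave 186 calls, and ALB had -2.09 (adjusted p = 0.212), HPD -0.40 (0.569) and TRIB1 1.00 (0.119). The split was 37 higher and 13 lower with normexp correction and 108 and 91 with quantile normalization, and no named gene kept its call in all 22 alternatives.

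The next question was which differences were present from 3 to 21 dpi. In the days stage some genes of plasma proteins were among those lower in challenged spleens. The fibrinogen chain genes FGA, FGG and FGB, which encode the clotting protein of plasma, fell by 3.64 ± 0.64, 2.53 ± 0.44 and 2.14 ± 0.47 (12.4-fold, 5.76-fold and 4.40-fold, n = 14 and 6, adjusted p = 0.00141, 0.00139 and 0.00806), each in 14 of 14 challenged arrays. PIT54, the hemoglobin-binding plasma protein of birds, fell 6.30-fold (-2.65 ± 0.52, adjusted p = 0.00336), and FETUB 5.83-fold (adjusted p = 0.000797). AMBP, the precursor of a plasma protease inhibitor, was at least 3.85-fold lower, since no challenged array was well above background (adjusted p = 0.000311). FABP1, the fatty acid binding protein of liver, fell 5.23-fold (adjusted p = 0.00552), and HABP2 and SLCO1A2 fell by 2.15 and 2.43. The beta-defensin gene AvBD9 fell by 2.85 ± 0.61 (7.21-fold, adjusted p = 0.00663), in 13 of 14 challenged arrays. Its level had a standard deviation of 3.86 over the 6 controls and 1.96 over the 14 challenged arrays, across times. The printed errors come from the spread within replicated groups and leave out that between lone controls. The neuronal genes GAP43 and KNDC1 fell by 2.13 and 2.61, near background. FETUB, HABP2 and KNDC1 were well above background on 1 of 14 challenged arrays and SLCO1A2 on 2, so their fall is imprecise. Without 12 dpi KNDC1 had -1.59 (adjusted p = 0.12) and SLCO1A2 -1.57 (0.00861).

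Rises in the days stage were smaller. FAM20C, a kinase of secreted proteins, rose by 1.36 ± 0.31 (2.57-fold, adjusted p = 0.0094), and DAB1, the reelin pathway adaptor, by 0.62 ± 0.13 (adjusted p = 0.00682). The detoxifying enzyme gene GSTA2 rose 1.51-fold (adjusted p = 0.0328), but by 0.30 (log2) without 21 dpi (adjusted p = 0.558), and the sugar kinase gene GALK2 rose 1.46-fold (0.54 ± 0.10, adjusted p = 0.00147) in 14 of 14 challenged arrays. CCNC, a cyclin of the Mediator complex, rose 1.40-fold (adjusted p = 0.00514) and the deacetylase gene SIRT1 1.31-fold (adjusted p = 0.0382). PCDHA6, CDCP2, SGCB, ATPAF1, OXNAD1 and TTF1 rose by 0.40 to 0.55. The other probe of FAM20C, of PCDHA6 and of CDCP2 had the opposite sign.

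Of the 26 liver markers 11 fell, or 14 adjusted over the list alone, with a median of -1.18 (adjusted p = 5.72e-08, and adjusted p = 0.129 with an estimated correlation). APOH, a phospholipid-binding plasma protein, fell by 1.23 ± 0.19 (adjusted p = 0.000623) and HPD by 1.13 ± 0.18 (adjusted p = 0.000529). In the acute phase list 6 of 17 members fell, and 6 adjusted over the list alone (adjusted p of the list = 0.0777). In the complement list C8A and C5AR1 fell by 1.53 and 0.61, and the list did not pass (adjusted p = 0.904). The embryonic globin gene HBZ fell by 0.96 ± 0.20 (adjusted p = 0.00454; erythroid list 0.747), GINS2 of DNA replication by 0.79 ± 0.21 (adjusted p = 0.0254; cell cycle list 0.677), and PLIN1 of fat droplets by 0.80 (adjusted p = 0.00659; muscle and stroma list 0.684). In the antimicrobial list AvBD9 alone of 31 members fell (adjusted p of the list = 0.684). In the complement, erythroid, cell cycle, muscle and antimicrobial lists the counts adjusted over the list alone were equal to these.

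The inflammatory list had a median of 0.01 in the days stage (adjusted p = 0.255). The NF-kB list passed with a median of 0.05 and no member past the test (adjusted p = 0.0285, and adjusted p = 0.697 with an estimated correlation), and quantile normalization gave 0.184. The median difference of all genes in this stage was -0.09. In the pancreas list 18 of 19 members were higher, none past the test, with a median of 0.57 (adjusted p = 0.0131, and adjusted p = 0.795 with an estimated correlation). That list had scores of 8.74 and 8.41 in 2 challenged arrays (3 dpi replicate 1 and 7 dpi replicate 2), and without the arrays with high scores its direction turned (adjusted p = 0.0916). The adjusted p of the others were 0.0777 for pattern receptors, 0.67 for interferon-stimulated genes, 0.255 for iron handling, 0.853 for antigen presentation, 0.684 for T and NK cells, 0.0515 for B cells, 0.0752 for macrophages, 0.158 for thrombocytes and 0.262 for heat shock.

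In all 80 genes were called higher and 1395 lower in the days stage, and with slide as a random block fewer were called, as given below. Quantile normalization gave 76 and 311, normexp correction 15 and 109, and the deposited values 72 and 285. The calls were among dim genes: of 5 brightness classes the dimmest pair held 867 and 352 of the lower genes and the brightest pair 37 and 32. The dimmest class had a median difference of 0.22 at 2 hpi and 0.13 at 4 hpi, when all arrays were scanned on 1 day, and of -0.24 to -0.64 from 8 hpi on. FAM20C lost its call with normexp correction (adjusted p = 0.466), and SLCO1A2 (0.125), FGB (0.0595), GSTA2 (0.0871) and SIRT1 (0.0848) lost theirs with quantile normalization. Without 5, 12 or 21 dpi 931, 723 and 753 genes were called, and without challenged replicate 1 or 2 of all times 831 and 796.

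**Figure D2:**
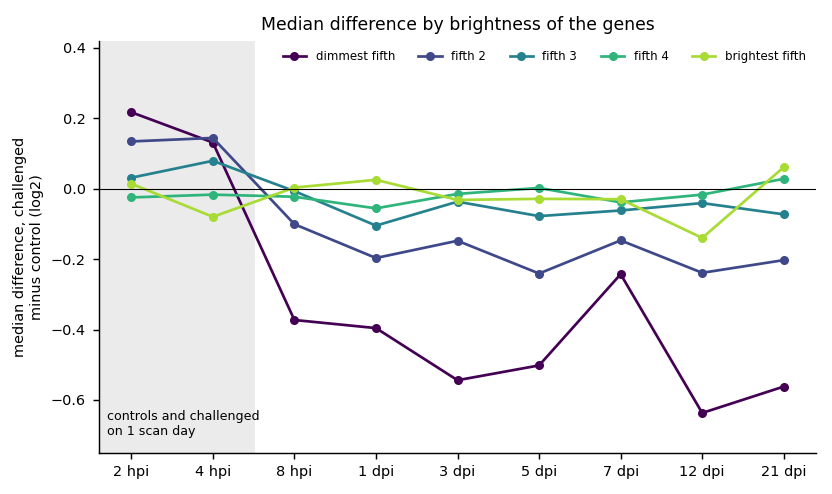
Median difference between challenged and control arrays (log2, y axis) at each time (x axis) for genes in 5 classes of mean brightness, 1 line per class; grey marks the times at which both groups were scanned on 1 day. The dimmest class lies at 0.22 at 2 hpi and at -0.56 at 21 dpi, and the brightest class lies between -0.14 and 0.06.

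Single times were compared next, to see which genes differed as the infection went on. At 2 hpi ALB was 37.1-fold lower (a difference of -5.21 ± 0.91, n = 3 and 1, adjusted p = 0.0161), the ceramide synthase gene LASS4 14.7-fold lower (adjusted p = 1.67e-06) and NMNAT2 of NAD synthesis 14.2-fold lower (adjusted p = 0.0208), while the transglutaminase gene TGM6 was at least 2.21-fold higher (adjusted p = 0.00889). At 4 hpi the matrix protease gene MMP7 was 92.5-fold lower (-6.53 ± 1.17, adjusted p = 0.034), GPRIN2 9.85-fold lower (adjusted p = 0.0312), and the Ig-like receptor gene CHIR-B2 at least 1.77-fold higher (adjusted p = 0.0206). The lone 4 hpi control array had the pancreas score of 6.41 and the lone 2 hpi control the liver score of 2.81, so the falls at these times rest on arrays that stood apart for another tissue. Up to 12 dpi each time had a lone control array, so a single odd spot on it can give a call. At 8 hpi the muscle creatine kinase gene CKMT2, the yolk protein gene VTG2 and the transcription factor gene EBF2 were lower, by at least 38.3-fold, at least 12.5-fold and 48.6-fold (adjusted p = 0.00767, 0.0114 and 0.00453). At 1 dpi the connexin gene GJA10 was at least 10-fold lower (adjusted p = 0.00501), SLCO1A2 14.3-fold lower (adjusted p = 0.00185) and the histone gene HIST2H3D 13.8-fold lower (adjusted p = 0.0478, and 0.0693 with the patch masked). HINT2, RALB and BAZ2B were called higher at 1 dpi by 11.89, 11.45 and 9.99, with their control spots in the patch. With the patch masked HECW2 was the highest named gene, 10.2-fold higher (3.35 ± 0.34, adjusted p = 1.98e-05), together with FGF6 at 2.92-fold.

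At 3 dpi the adhesion gene NCAM2, the water channel gene AQP11 and ASB15 were lower by at least 7.63-fold, 9.32-fold and 4.42-fold (adjusted p = 0.0457, 0.00443 and 0.000183). At 5 dpi the cell cycle gene CDCA4 rose 2.52-fold (1.33 ± 0.23, adjusted p = 0.0102), whereas the pigment enzyme gene DCT, the melatonin receptor gene MTNR1B and AMBP were lower by at least 21.4-fold, 44-fold and at least 15.4-fold (adjusted p = 0.000118, 0.00305 and 0.0218). At 7 dpi ETFA of mitochondrial electron transfer rose 2.42-fold (1.28 ± 0.20, adjusted p = 0.00469), and the integrin gene ITGB8, the semaphorin gene SEMA6D and the adaptor gene SH2B2 fell 19.9-fold, 9.91-fold and 7.65-fold (adjusted p = 0.00431, 0.000846 and 0.0121). At 12 dpi GVINP1, of the interferon-induced giant GTPases, was called at least 83-fold higher (adjusted p = 0.000167), but this rests on 1 spot at background on the lone control array. RNASEH2B rose 2.49-fold (adjusted p = 0.0357), the glutamate transporter gene SLC17A6 fell by 6.74 ± 1.03, and LRRC9 and KNDC1 were at least 26-fold and at least 30-fold lower (adjusted p = 0.00357, 0.000384 and 0.00366). At 21 dpi, with 2 and 2 arrays, the hexokinase gene HKDC1, DNER and the retinoic acid binding gene CRABP1 rose 4.42-fold, 4.22-fold and 4.03-fold (adjusted p = 0.00684, 0.0328 and 0.034), and NR2E1, GABRA3 and the adhesion gene IGSF11 fell 24.8-fold, 20.3-fold and 13-fold (adjusted p = 0.00903, 0.0408 and 0.00452). Without control array 26 the differences of NR2E1, GABRA3 and IGSF11 were -2.20, -1.53 and -3.36 (0.0467, 0.471 and 0.0588), and without control array 25 they were -7.06, -7.16 and -4.03.

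NMNAT2, GPRIN2, EBF2, SLCO1A2, MTNR1B and SLC17A6 were well above background on 1 of 3 challenged arrays in these comparisons, and NR2E1 and GABRA3 on 1 of 2, so their folds are imprecise. The other probe of DCT, of MTNR1B and of SLC17A6 had the opposite sign. The numbers called higher and lower were 3 and 27 at 2 hpi, 1 and 12 at 4 hpi, 1 and 23 at 8 hpi, 56 and 71 at 1 dpi, 1 and 30 at 3 dpi, 1 and 52 at 5 dpi, 3 and 23 at 7 dpi, 2 and 71 at 12 dpi, and 78 and 285 at 21 dpi. At 1 dpi 39 of the 56 rises lay in the patch, and 13 higher and 45 lower were left without it, while normexp correction gave 44 and 35 and the deposited values 81 and 66. The splits were 14 and 42 at 2 hpi, 5 and 22 at 4 hpi, 2 and 15 at 12 dpi and 64 and 70 at 21 dpi with quantile normalization, and 73 and 55 at 21 dpi with normexp correction. The median difference of all genes was -0.15 at 12 dpi, -0.11 at 5 dpi and -0.10 at 1 dpi before quantile normalization, and -0.02, -0.01 and -0.08 after it. Leaving out challenged replicate 2 or 3 at 12 dpi gave 35 and 39, replicate 1 or 2 at 4 hpi gave 8 and 3, either challenged array at 21 dpi gave 108 and 127, and either of its controls gave 55 and 67. In fits to the arrays of a single time limma called 0 genes at 2 and 8 hpi and at 3, 5, 7 and 12 dpi (1139 to 4067 at an unadjusted p under 0.05), 24 at 1 dpi and 2872 at 21 dpi. With normexp correction TGM6, CHIR-B2, GPRIN2, VTG2, NCAM2, AQP11, ASB15, DCT, DNER, CRABP1, NR2E1 and GABRA3 were no longer called. MTNR1B at 5 dpi (0.52) and SLCO1A2 at 1 dpi (0.04) turned positive with normexp correction, and NR2E1 at 21 dpi (2.25) did in the deposited values.

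**Figure D3:**
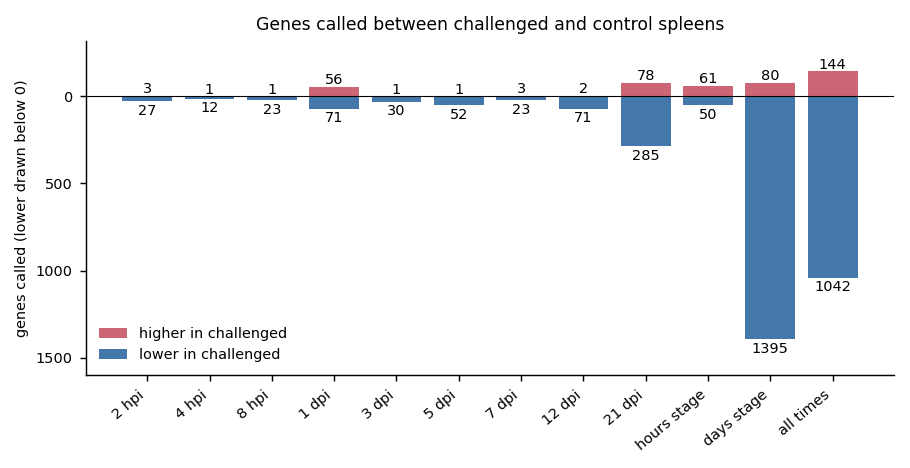
Number of genes called (y axis; higher in challenged above 0, lower drawn below 0) for each time, each stage and all times (x axis), with the number at each bar. The days stage has 80 higher and 1395 lower, and 39 of the 56 rises at 1 dpi lay in the patch.

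Over all 9 times 144 genes were called higher and 1042 lower, and the median difference of those called was 0.74 in size. TRIB1 and HECW2 were among those higher (0.40 and 0.42, adjusted p = 0.0425 and 0.0325) and LASS4 was among those lower (-0.48, adjusted p = 0.00732); these were picked after their values were seen. The means rest largely on single times for HECW2 (3.35 at 1 dpi) and LASS4 (-3.88 at 2 hpi). Quantile normalization gave 194 higher and 336 lower, normexp correction 44 and 74, and the deposited values 194 and 314. Without 12 or 21 dpi 588 and 624 were called, and without challenged replicate 1 or 2 of all times 661 and 560. Without the arrays with high pancreas or liver scores 1949 were called, but this also dropped 2 and 4 hpi, whose lone controls were among those arrays. The additive model called 922, and 8 (2 higher and 6 lower) with the scan day as a further term. With slide as a random block fewer were called than in the main fit, as given below.

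Whether the effect of the challenge differed between the stages was tested directly. GPRIN2 had a higher difference in the days stage by 2.06 ± 0.38 (adjusted p = 0.0138) and LASS4 by 1.23 ± 0.20 (adjusted p = 0.00493), and YPEL1 and NUDT19 by 0.60 and 0.50 (adjusted p = 0.0455 and 0.0488). YPEL1 and NUDT19 lost their calls with the patch masked (0.0726 and 0.0758). GPRIN2 had 1.46 without 4 hpi (0.171) and 1.68 without 12 dpi (0.136). LASS4 rested on 2 hpi, without which the value was 0.33 (adjusted p = 0.623). HINT2, RALB, BAZ2B, MAF, CRYBA1, OSBP2, CAPN10 and STX2 were called lower by -3.08, -2.83, -2.69, -2.37, -2.27, -2.24, -2.16 and -2.10, all with their 1 dpi control spot in the patch. With the patch masked 2 genes were higher and 32 lower. The falls with a symbol were GSG1 (-1.87, adjusted p = 0.0365), IL5, a cytokine of type 2 immunity (-1.62 ± 0.30, 0.031), DOLPP1 (-1.15, 0.031) and MOGAT2 of fat absorption (-0.93 ± 0.15, 0.0224). These genes lie outside the rule for named genes and were not checked without single times.

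The pancreas list differed between the stages with a median of 1.86 (adjusted p = 0.00459, and adjusted p = 0.857 with an estimated correlation; 0.381 without the arrays with high scores). The inflammatory list had a median of -0.69 and did not pass (adjusted p = 0.0667). In the macrophage list MAF alone was called, from the patch, the NF-kB list had 1 member lower adjusted over the list alone, and the adjusted p of the lists other than pancreas and inflammation lay between 0.365 and 0.896. In all 6 genes were higher and 84 lower (90 of 24966, 3377 at an unadjusted p under 0.05). Quantile normalization gave 12 and 52, normexp correction 0 and 27, and leaving out 2, 4 or 8 hpi or 7, 12 or 21 dpi gave 50, 56, 163, 141, 51 and 51. Without challenged replicate 1 or 2 of all times 35 and 48 were called. Without the arrays with high scores, and so without 2 and 4 hpi, 54 were. With slide as a random block fewer were called too, as given below.

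The control arrays alone were used to compare the uninfected spleen between the hours and days stages, from an age of 2 days to one of 4 to 21 days by the labels, whose ages do not all equal the challenge day plus the time. The 4 hours-stage controls lay on 1 slide and the 6 days-stage controls on others, so in the controls alone stage and slide coincided. GZMA, a protease of cytotoxic lymphocyte granules, rose by 4.18 ± 0.61 (18.1-fold, n = 6 and 4, adjusted p = 0.0011). IL4I1 rose 19-fold (4.25 ± 0.43, adjusted p = 0.000417), ACOD1, the itaconate enzyme of activated macrophages, rose 12.6-fold (3.66 ± 0.47, adjusted p = 0.000746), and the chemokine receptor gene CXCR4 rose 9.38-fold (adjusted p = 0.00272). The defensin genes AvBD7, AvBD6, AvBD1 and DEFB4A, which heterophils express, rose 21.3-fold, 14.2-fold, 13.5-fold and 17.6-fold (adjusted p = 0.0245, 0.027, 0.019 and 0.0195). JCHAIN, which links polymeric antibodies, rose 12.6-fold (3.66 ± 0.75, adjusted p = 0.00432), and TNFRSF13B, a receptor of B cells for survival factors, rose 9.78-fold (adjusted p = 0.000751). CMBL and DCSTAMP rose 10.9-fold and 8.80-fold.

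CNTN2, an adhesion protein of neurons, fell by 5.00 ± 0.85 (32-fold, adjusted p = 0.00188), and the epithelial adhesion gene EPCAM fell 14.4-fold (-3.85 ± 1.32, adjusted p = 0.0397), but without the 21 dpi controls by 2.24 (0.0686). AvBD7, DEFB4A, AvBD6, AvBD1 and ATP12A lost their calls without these controls too (0.0721, 0.0608, 0.0779, 0.0596 and 0.071). In each challenged group with a high pancreas score in 1 array, EPCAM was highest in that array (0.19 against -4.14 and -8.75 at 7 dpi). CNTN2 was so at 7 dpi (-3.29 against -7.20 and -8.89) but not at 1 dpi. In the 4 hpi control EPCAM had -0.36, against -2.83 to -1.57 in the other hours-stage controls. Whether carried-over tissue had a part in these falls was not tested. The synaptic adhesion gene LRRTM4 fell 10.9-fold (adjusted p = 0.000374). DKK1, a Wnt inhibitor, the homeobox gene DLX5 and the growth factor gene FGF18, all of use in embryonic patterning, fell 10.2-fold, 8.98-fold and 8.74-fold (adjusted p = 0.00131, 0.0023 and 0.00618). TECRL fell 9.98-fold, SERPIND1 9.79-fold and ATP12A 9-fold, and SLC7A13 and FSTL5 were at least 3.8-fold and at least 3.61-fold lower.

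Lymphocyte genes rose together in the controls. Of 33 T and NK cell markers 29 rose, or 31 adjusted over the list alone, with a median of 1.33 (adjusted p = 1.09e-15, and adjusted p = 0.111 with an estimated correlation). Examples were the chemokine gene XCL1 (2.69 ± 0.25), the cytotoxic granule gene GNLY (2.45 ± 0.27) and the T cell receptor adaptor gene TRAT1 (2.00 ± 0.22). Of 23 B and plasma cell markers 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.82 (adjusted p = 1.13e-06), among them IRF4 (2.13 ± 0.34) and POU2AF1 (2.98 ± 0.48), both needed in activated B cells. Of 18 antigen presentation genes 13 rose (14 adjusted over the list alone) with a median of 0.75 (adjusted p = 7.37e-08), B2M by 1.19 ± 0.12 and the peptide transporter gene TAP1 by 1.68 ± 0.20. Of 32 interferon-stimulated genes 20 rose (22 adjusted over the list alone) with a median of 0.80 (adjusted p = 1.74e-10), IRF1 by 1.34 ± 0.19, and of 45 cell cycle genes 25 rose (25 adjusted over the list alone) with a median of 0.61 (adjusted p = 1.74e-10, and adjusted p = 0.306 with an estimated correlation), AURKB by 1.41 ± 0.16 and TPX2 by 1.31 ± 0.14. With an estimated correlation the adjusted p of the B cell, antigen presentation and interferon lists was 0.111.

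Innate immune genes also rose. Of 32 inflammatory genes 17 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 1.04 (adjusted p = 1.09e-07), and of 31 antimicrobial genes 14 rose (15 adjusted over the list alone), with a median of 1.29 (adjusted p = 2.49e-06, and adjusted p = 0.199 with an estimated correlation). The oxidase subunit gene CYBB rose by 1.38 ± 0.17. Of 21 NF-kB genes 10 rose (11 higher and 1 lower adjusted over the list alone, median 0.41, adjusted p = 7.26e-06), and of 22 pattern receptors 12 rose and 2 fell (13 and 3 adjusted over the list alone, median 0.66, adjusted p = 0.00059), with the bird receptor gene TLR15 up by 2.11 ± 0.22 and the collectin gene COLEC11 down (-1.63 ± 0.14). Of 28 erythroid genes 14 rose and 2 fell (17 and 3 adjusted over the list alone, median 0.50, adjusted p = 0.000139, and adjusted p = 0.134 with an estimated correlation), HBA1 by 1.90 ± 0.39, while LMO2 of the same list fell by 1.40 ± 0.23. The macrophage list (10 rose, 4 fell, adjusted p = 0.00609), the complement list (6 rose, 1 fell, 0.0367) and the iron list (6 rose, 2 fell, 0.0242) passed, and lost their calls with quantile normalization (0.106, 0.174 and 0.0837). Their counts adjusted over the list alone were the same. With an estimated correlation the inflammatory, NF-kB, pattern receptor, macrophage, complement and iron lists had an adjusted p of 0.111. Of 26 muscle and stroma genes 8 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.53, adjusted p = 0.0227, and adjusted p = 0.451 with an estimated correlation; 0.195 with normexp correction), the muscle creatine kinase gene CKM falling by 1.83 ± 0.13 and FN1 rising by 1.65 ± 0.30. The acute phase list did not pass (adjusted p = 0.383) and had a median of -0.31 against an upward test, and thrombocyte, heat shock, pancreas and liver lists gave 0.9, 0.257, 0.123 and 0.268. No list in any comparison held its call with an estimated correlation.

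**Figure D4:**
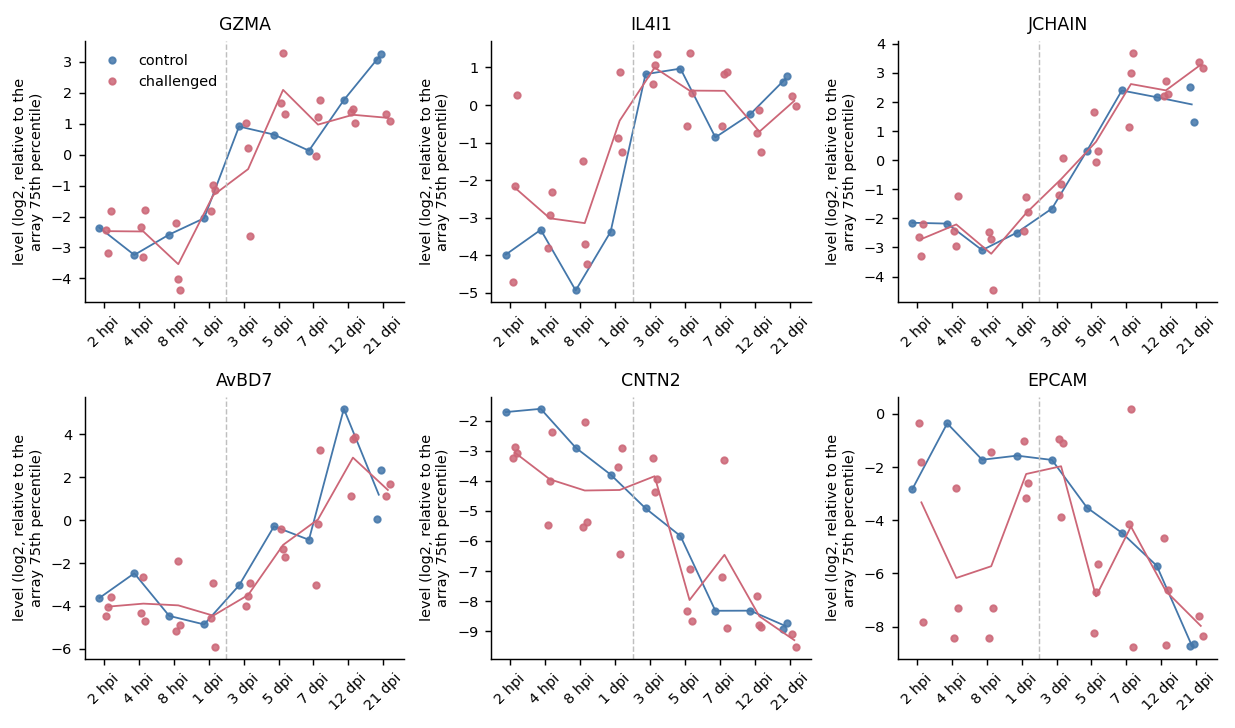
Level of 6 named genes (log2 relative to the 75th percentile of the array, y axis) at each time (x axis), with 1 point per array, lines through the group means and a dashed line between the stages. GZMA, IL4I1, JCHAIN and AvBD7 rose and CNTN2 and EPCAM fell between the stages in the control arrays, with the 4 rises between 3.66 and 4.41 and falls of 32-fold and 14.4-fold.

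In the controls 3568 genes were called higher and 6479 lower in the days stage, with a median change of all genes of -0.15, and in the challenged arrays 5871 and 11848, with a median of -0.28. Both comparisons called 3105 genes higher (837 if the calls were independent) and 5878 lower (3068), and 8 and 5 were called in opposite directions. The correlation of the changes across genes, which are not independent replicates, was 0.838. In the controls the balance turned with brightness. The dimmest of 5 classes had 141 higher and 1240 lower (median change -0.46), and the brightest had 1487 and 803 (median change 0.15). The days-stage controls also had higher 75th percentiles (1529 to 2082) than the hours-stage controls (800.5 to 1407). The slope fitted to the spike-in probes was 0.8929 to 0.9405 in the hours-stage controls and 0.9494 to 0.9799 in the days-stage controls, without overlap. Whether signal level or this difference in response had a part in the age change was not tested. Normexp correction gave 3577 and 11875 in the controls, with a median of -0.32, and quantile normalization 7166 and 8251 in the challenged arrays, with a median of -0.05. Without the arrays with high pancreas or liver scores, which took out the 2 and 4 hpi controls, 3745 genes were called in the controls. AvBD7 (adjusted p = 0.086) and EPCAM (0.174) were not among these genes. With slide as a random block 6178 were called, without AvBD7 (0.0907), AvBD6 (0.0974), AvBD1 (0.0746), DEFB4A (0.0752) and EPCAM (0.0693). A model of 2 stages in place of the group means called 16329 in the challenged arrays, and 11468 with the scan day as a further term.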

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

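The tests of the patch, of the splits without the patch, of the dim genes, of the scan day, of a response, of pancreas tissue and of an effect on the pancreas signal were chosen only after the result was seen. The test of liver tissue was set before its value but after the liver scores were seen, and the other counts of splits were planned.

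Outliers were sought among the control arrays of each stage, with 94 tests of list scores, signal measures and named genes, of which 6 stood apart where chance gives about 1 in 20 (4.7). The pancreas list score was 6.412 in the 4 hpi control array, against -0.234 to 0.799 in the other hours-stage controls. The score of the W-linked genes was -0.6 in the 8 hpi control pool, against 0.318 to 0.406. The 75th percentile of the processed intensity was 2082 in control array 25 of 21 dpi, against 1529 to 1618 in the other days-stage controls. ACOD1 had a level of 0.785 in the 7 dpi control, against 2.326 to 3.072. In the 1 dpi control DLX5 had a level of -3.508 (others -2.712 to -2.634) and FGF18 one of 2.272 (others 0.807 to 0.991).

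The challenge effect differed between the stages, by the test of the difference itself, for 90 genes. GPRIN2, LASS4, YPEL1 and NUDT19 were higher in the days stage by 2.055, 1.231, 0.601 and 0.498. HINT2, RALB, BAZ2B, MAF, CRYBA1, OSBP2, CAPN10 and STX2 had values of -3.076, -2.832, -2.693, -2.37, -2.272, -2.244, -2.162 and -2.101, and the pancreas list one of 1.863. That list lost its call with an estimated correlation (adjusted p = 0.857) and without the arrays with high scores (0.381). When arrays were split again within each time, 3 of 100 splits gave as many genes in the stage difference, the real one included (80 among the 24583 genes used, highest other 333). The patch described below carries 32 of the 84 falls in the stage difference, and without its genes 4 of 100 splits gave as many (real 29, highest other 330). Both shares lie under the limit of 5 of 100 that was set for excluding chance. The highest other split had several times the real count in each case, so this exclusion is weak. What made those splits large was not tested. For the hours stage 5 of 100 splits were as large (real 109, highest other 177), and 6 of 100 without the genes of the patch (real 33, highest other 177), so chance is not excluded there. For the days stage and for all times 1 of 100 was, the real one (1401 and 1127, highest others 219 and 132), and chance is excluded as the reason for the counts.

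The first pattern was a set of rises at 1 dpi of up to 11.89 (log2). On the 1 dpi control array 57 spots far under their median level lay side by side, against 0 on the other 35 arrays. The same genes had 25 probes of 15 genes outside the patch, and these gave a median difference of -0.003 at 1 dpi. The spots inside gave 6.446, so lower transcript levels in that control pool are argued against, and a patch of spots without signal is a candidate cause. Masking it left 58 of the 127 calls at 1 dpi; no other biological explanation was tested.

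The second pattern was the excess of falls in the days stage. Of the genes called lower 12.6% lay in the brighter 3 of 5 brightness classes, which hold 60% of all genes, so dimness may account for much of the count. A shift of dim signals between the scan days cannot be told apart from the challenge, since both change together from 8 hpi on: the same genes had a median of 0.227 at 2 and 4 hpi and -0.583 at 8 hpi and 1 dpi. Liver tissue in the control pools stays open too, with 12.8% of the falls following the liver score at a correlation over 0.7 against 0.984% of all genes. This contrast cannot weigh for liver tissue. The falls were chosen as lower in the challenged arrays, where the liver list also lay lower, and 11 of them are members of that list. A response to the challenge also stays open, with 57 genes lower when the 15014 brighter genes were fitted alone (highest other split 18), because no time of the stage had both groups scanned on 1 day.

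The third pattern was the pancreas signal of 5 arrays, with scores of 6.41 (control 4 hpi), 5.00 (challenged 8 hpi replicate 2), 2.94 (1 dpi replicate 1), 8.74 (3 dpi replicate 1) and 8.41 (7 dpi replicate 2). In each of them at least 78.9% of the 19 members were over 1 above their median, and the order of the members was shared (rank correlations of at least 0.733), so pancreas tissue carried over at dissection is a candidate source. CPA1, CEL and INS of exocrine and endocrine cells reached levels of 7.97, 4.29 and 3.50 in the 3 dpi array. An effect of the challenge or of the time is argued against, since 0 of the 8 other arrays of these groups had a score over 2 (highest 0.041). The 4 hpi control had no other array in its group, so this does not cover it.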

How the results depend on the processing

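The tests with a slide block at single times and for the lists, a scan day term, the masked patch, the brighter classes and without the arrays with high pancreas or liver scores or the dimmest array were chosen only after the result was seen, and the others were planned.

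Quantile normalization gave 56 genes at 2 hpi, 27 at 4 hpi, 17 at 12 dpi, 134 at 21 dpi, 199 in the hours stage, 387 in the days stage and 530 over all times. Normexp correction gave 13 at 8 hpi, 79 at 1 dpi, 19 at 3 dpi, 17 at 7 dpi, 37 at 12 dpi, 128 at 21 dpi, 50 in the hours stage, 124 in the days stage, 118 over all times, 27 for the stage difference and 15452 for the control age change. The deposited values gave 52 at 2 hpi, 27 at 4 hpi, 28 at 5 dpi, 19 at 12 dpi, 131 at 21 dpi, 201 in the hours stage, 357 in the days stage and 508 over all times. With no filter 24 were called at 4 hpi, 46 at 8 hpi, 52 at 3 dpi, 41 at 7 dpi and 119 at 12 dpi. Genes well above background on at least 18 arrays gave 8 at 4 hpi, 11 at 8 hpi, 15 at 3 dpi, 28 at 5 dpi, 15 at 7 dpi, 21 at 12 dpi, 200 at 21 dpi, 672 in the days stage and 497 over all times, from fewer genes tested. An added log2 difference of at least 1 left 60 in the hours stage, 724 in the days stage, 268 over all times, 3560 for the control age change and 5896 for the challenged one. Trend and robust options gave 59 for the stage difference.

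With slide as a random block (consensus correlations 0.086, 0.178 and 0.065) limma called 7 at 4 hpi, 138 at 21 dpi, 40 in the hours stage, 799 in the days stage, 522 over all times, 38 for the stage difference and 6178 for the control age change. Fits to the arrays of that time alone gave 0 at 2 and 8 hpi and at 3, 5, 7 and 12 dpi, 24 at 1 dpi and 2872 at 21 dpi. The additive model gave 0 in the hours stage (2353 at an unadjusted p under 0.05), and with the scan day 0 in the hours stage (1565) and 8 over all times, against 922 over all times without it. A model of 2 stages gave 16329 for the challenged age change, and 11468 with the scan day as a further term, while the first scan day alone gave 17 in the hours stage. The masked patch left 58 at 1 dpi, 38 in the hours stage and 34 for the stage difference. The brighter 3 of 5 classes gave 69 in the days stage and 118 over all times. Without the arrays with high scores 186 were called in the hours stage, 1949 over all times, 54 for the stage difference and 3745 for the control age change. This setting took out the lone controls of 2 and 4 hpi, so its hours stage held 8 hpi and 1 dpi alone. With an estimated correlation 0 of 76 list tests passed.

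Without 1 dpi 11 were called in the hours stage. Without 5, 12 and 21 dpi the days stage gave 931, 723 and 753, and without 12 and 21 dpi all times gave 588 and 624. The stage difference gave 50, 56, 163, 141, 51 and 51 without 2, 4 and 8 hpi and 7, 12 and 21 dpi. Leaving out a replicate in turn gave 22 to 35 at 2 hpi, 3 to 11 at 4 hpi, 20 to 36 at 8 hpi, 97 to 152 at 1 dpi, 22 to 28 at 3 dpi, 38 to 47 at 5 dpi, 19 to 26 at 7 dpi, 35 to 102 at 12 dpi, 55 to 127 at 21 dpi, 35 to 153 in the hours stage, 796 to 1757 in the days stage, 560 to 1559 over all times, 35 to 103 for the stage difference, 7469 to 10332 for the control age change and 14023 to 17280 for the challenged one. Without challenged replicate 1 of all times 831 genes were called in the days stage and 661 over all times, and without replicate 2 44 in the hours stage and 48 for the stage difference. The replicate block gave 17635 for the challenged age change, and the numbers did not pair the arrays: 84 pairs with the same number had a mean correlation of -0.001 after group means were removed, and 168 other pairs one of 0.001.

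Reversed in sign were RALB in the stage difference without 1 dpi (0.016), SLCO1A2 at 1 dpi (0.041) and MTNR1B at 5 dpi (0.519) with normexp correction, and NR2E1 at 21 dpi in the deposited values (2.248). Reversed in direction were the pancreas list of the days stage without the arrays with high scores (adjusted p = 0.0916) and the heat shock list of the hours stage on the first scan day (adjusted p = 0.471). Apart from the filters, the added threshold and the masked spots, the cause was not tested. Of the values of named genes under alternatives 1607 kept direction and call, 543 lost the call and 4 reversed. In the control age change 16 of 24 named genes never lost their call, in the days stage 5 of 24 and in the hours stage 0 of 24. Dim signals are a limit of the days stage, since 867 of its 1395 falls lay in the dimmest of 5 classes. In the control age change the balance of rises and falls also turned with brightness.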

Other observations

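The tests of secretory genes and of slides below were chosen only after the result was seen, and the immunoglobulin features, globins and developmental genes named here were picked after their values were seen, while the splits were planned.

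Antibody transcripts rose between the stages. Of 80 features that the array file describes as immunoglobulin, 67 rose and 2 fell in the control arrays from the hours to the days stage, with a median change of 5.41 (log2), and 73 rose in the challenged arrays with a median of 5.62. Of 42 light chain features 41 rose in the controls, with a median of 5.98, the mu heavy chain rose by 5.45, and 3 IgG heavy chain features rose by a median of 6.00 and the IgA heavy chain by 2.88. Of 33 heavy chain variable region features 21 rose, with a median of 2.35. The median level of the 80 features was -4.64 in the 2 hpi control, -3.68 at 3 dpi, -0.39 at 5 dpi, 2.07 at 7 dpi, 2.52 at 12 dpi and 2.10 at 21 dpi. In challenged arrays it was -4.06 at 2 hpi, -2.32 at 3 dpi, 0.23 at 5 dpi, 2.37 at 7 dpi, 2.08 at 12 dpi and 3.50 at 21 dpi. No feature was called between challenged and control arrays in either stage, in the stage difference or at a single time up to 12 dpi. At 21 dpi, with 2 and 2 arrays, limma called 4 of the 80 higher in challenged arrays, with a median difference of 1.25.

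Some globin genes rose as well, HBA1, HBAD and HBBA of the later and HBE of the early hemoglobins by 1.90 ± 0.39, 2.32 ± 0.52, 1.67 ± 0.42 and 1.88 ± 0.45 in the controls (adjusted p = 0.00434, 0.00653, 0.0104 and 0.00871) and by 1.58, 1.93, 1.44 and 1.64 in the challenged arrays. HBBR rose too (1.85, adjusted p = 0.0137), and HBE1 (1.41, 0.115) and HBZ (-0.30, 0.198) were not called in the controls. Some genes of early development and stem cells fell, among them DNMT3B, which sets DNA methylation, by 1.65 ± 0.14 (adjusted p = 0.000321), the progenitor and vessel gene CD34 by 1.77 ± 0.26, the endothelial factor gene SOX18 by 1.54 ± 0.18 and the fetal RNA-binding gene IGF2BP1 by 1.46 ± 0.37. LIN28B and IGF2BP3 of the same kind were not called in the controls (-0.31 and 0.15, adjusted p = 0.465 and 0.503). The cartilage collagen genes COL9A1 and COL11A1 fell by 2.22 and 1.49. In the challenged arrays DNMT3B, CD34, SOX18 and IGF2BP1 had changes of -1.99, -1.96, -2.03 and -2.32.

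More antibody-secreting cells in the older spleens could account for the immunoglobulin change, as a hypothesis. In the controls 9 of 12 genes of the secretory machinery of plasma cells rose with a median of 0.68, and 5 of 11 B cell genes with a median of 0.69. The difference of the medians was -0.012, which decides neither for secretory cells nor for B cells as a whole.

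The age changes were larger than in other splits. For the controls 1 of 100 splits drawn from 210 was as large, the real one (9890 genes, highest other 21), and for the challenged arrays 1 of 100 was (17387, highest other 9194), so chance is excluded for both counts. In the controls the stage coincided with the slide. Between the challenged arrays of 1 and 3 dpi that shared a slide (2 and 2), 76.6% of the genes called higher and 73.1% of those called lower in the controls changed in the same direction, against 47.1% and 52.9% of all genes. These shares argue against a difference between slides as the whole cause of the directions. They do not cover the size of the changes. The called genes had median changes of 0.211 (rises) and -0.293 (falls) there. The control calls had a median size of 0.811, over a longer span of age. How much of that size came from the slides stays open. The arrays of 1 and 3 dpi also differed in the course of infection.

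At 1 dpi, tested on its own after the values were seen, the inflammatory list had 29 of 32 members higher with a median of 1.08 (adjusted p = 2.26e-07, and adjusted p = 0.462 with an estimated correlation), and the T and NK cell list 29 of 33 with a median of 0.59 (adjusted p = 1.26e-05, and adjusted p = 0.496 with an estimated correlation). The cell cycle list had 43 of 45 higher with a median of 0.56 (adjusted p = 1.55e-10, and adjusted p = 0.496 with an estimated correlation). At 3 dpi 0 of 45 cell cycle members were higher (median -0.73), and at 8 hpi 3 were (median -0.70). The NF-kB, antigen presentation, pattern receptor, interferon and macrophage lists also lay higher at 1 dpi (adjusted p = 2.83e-05, 0.00234, 0.0117, 0.0141 and 0.0141). No list passed there with an estimated correlation, and the groups were scanned on different days. A single control array stood behind each of these times.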
